A study of Mus musculus with 6 samples.

How the data were processed

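RNA was measured by sequencing in 6 samples of mouse long-term haematopoietic stem cells, 3 labelled wild type and 3 labelled Zcchc8 KO. Per the labels' protocols, marrow was crushed from leg and hip bones, red cells were lysed, lineage-positive cells were depleted, and 1500 cells per sample were sorted, with cDNA amplification before a transposase library kit; the surface markers of the sort gate are not given in the sources used here. Groups were taken from the sample titles, as were the replicate numbers. Per the submitters' processing notes, the tools named are fastp, Bowtie2 and featureCounts and the build is mm10, with no versions. The deposited values are FPKM per gene symbol, in 1 table of 14986 genes and 6 columns, as the authors made them. Strand use and the treatment of reads with several matches are not given in the sources used here, so genes that overlap or have near-identical copies are uncertain. Bowtie2 does not split reads over introns, which lowers values over exon junctions and can move reads to processed pseudogenes.

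Symbols were matched to the GENCODE M21 annotation of GRCm38, the assembly of mm10, for 14693 genes (98.0%), which gave identifiers, coordinates, biotypes and exon lengths. For matched genes, FPKM times exon length was read as a multiple of 1 step per library, and 97.9% of the values below 100 reads came out whole within 0.05. The steps gave the reads behind the FPKM of each library, from 18065542 to 25716196. On a 2 kb gene 1 read is worth 0.0194 to 0.0277 FPKM. The values carry no molecular identifiers, and amplified cDNA from few cells repeats molecules, so reads overstate the number of independent molecules. All genes but 1 are above 0 in at least 4 libraries, and the remaining one in 3.

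Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 11837 in all, on log2(FPKM + 1), which understates the change of low genes. KO was compared with wild type in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Every adjusted p of a gene is from limma. Fold changes are ratios of mean FPKM. The 41 gene lists, 34 of symbols and 7 of symbol patterns, were tested by limma's camera with a preset correlation of 0.01. Lists with at least 5 tested members were used, 38 in all, with adjustment over the lists. The 9 classes by biotype, exon number and gene span, which overlap in part, were tested in the same way and adjusted over the classes alone. With an estimated correlation 3 lists passed, of which 2 were among the 11 that passed with the preset one, the respiratory chain and the list of monocytes, macrophages and dendritic cells. Among lists that lost the call, the estimate was above the preset value for erythroid, proteasome, nuclear lncRNA and ribosome biogenesis genes. It was below it for T and NK cells (-0.214), B cells (-0.128), granulocytes (-0.032), LT-HSC identity (-0.024) and lymphoid priming (0.006). A higher correlation does not account for the loss in these. By fry, which tests whether a list's genes move one way on balance, 8 passed, 7 of them among the 11. The lists, the test, the rule for named genes and most alternatives were fixed before the data were examined.

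The text names Zcchc8; the 12 largest rises and falls among genes with an adjusted p under 0.05, a mean of at least 5 FPKM in the higher group and groups that do not overlap, leaving out predicted symbols; where a direction had fewer than 8, those of smallest p to fill it; the 4 members of smallest p of each list past its threshold and up to 3 passing members of other lists; and 5 complex partners and exosome genes. Some of the genes that this rule takes are not reported here. The procedure was tested on 10 simulated tables of the 11837 genes with 200 genes changed, of which 19.5% were recovered at a log2 change of 1 and 61.6% at 2, with 4.6% of calls false and 0 of wrong sign. Alternatives changed the pseudocount, the filter, the scaling, the variance model, the block and the libraries used, and left out ribosomal protein and mitochondrial genes before rescaling the rest to a fixed total, and later ones used voom on recovered reads, equal depth by thinning, a correction for GC content and exon length, and no pseudogenes. Replicates of a group differed by more than the counting error of reads, with a chi-square per gene of 54.5 to 77.7 on recovered reads. This covers counting error only and does not show whether libraries came from separate cells or animals. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No mitochondrially encoded gene is in the table used here, so that list was not tested.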

Results

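Polyadenylated RNA was sequenced from long-term haematopoietic stem cells, the marrow cells at the top of the blood hierarchy, sorted from mouse bone marrow after lineage depletion. The 6 libraries, each made from 1500 sorted cells, comprised 3 labelled wild type and 3 labelled Zcchc8 KO. ZCCHC8 is the scaffold of the nuclear exosome targeting complex, which hands short-lived nuclear transcripts to the RNA exosome, and the comparison asks what its loss does to the transcriptome of these cells. The table listed 14986 genes in FPKM. The reads behind these values came to 18065542, 18298931 and 18915749 in the wild-type libraries 1 to 3, and to 25716196, 18969573 and 20829862 in the KO libraries. Nothing in the labels says that the replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical.

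Zcchc8 itself (chromosome 5, 123698294 to 123721100, GRCm38, minus strand) was not lower in the libraries labelled Zcchc8 KO. It stood at 8.93, 5.24 and 5.16 FPKM in wild type and at 10.40, 5.54 and 5.92 FPKM in KO, a log2 change of 0.15 ± 0.33 (SE). The exact two-sided permutation test gave p = 0.5, with 0.1 the smallest p that 3 libraries against 3 allow, and the limma adjusted p was 0.94. One value per gene, summed over all exons, cannot show the deletion of single exons, so the expression table does not check the labels, and every direction below is that of the libraries labelled KO. The complex partners Rbm7 and Mtrex differed by less than the spread between replicates. Rbm7 measured 37.1 ± 2.52 FPKM in wild type and 37.8 ± 5.90 in KO (SD, n = 3), and Mtrex, the RNA helicase, 5.36 ± 1.25 and 5.43 ± 1.47. Among exosome factors, Exosc10 (12.4 ± 2.35 and 14.8 ± 1.89), Dis3 (2.24 ± 0.255 and 2.54 ± 1.10) and the adaptor Zfc3h1 (2.08 ± 1.29 and 3.87 ± 0.984) did not pass the test. None of the 28 tested genes of the list of complex partners, nuclear exosome and cap-linked adaptors passed, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05, lower in KO (limma).

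In the comparison of KO with wild type, the largest rises among the genes that passed the test were those of 4 genes of eosinophil granules. Prg2, the eosinophil major basic protein (chromosome 2, 84980461 to 84983632), was listed at 0, 0 and 0.379 FPKM in wild type and at 118.9, 129.3 and 131.6 FPKM in KO (adjusted p = 2.08e-06). Its neighbour and homologue Prg3 (chromosome 2, 84988215 to 84993886) went from 0.117, 0 and 0 to 15.5, 14.3 and 14.5 FPKM (adjusted p = 0.00082). Epx, eosinophil peroxidase, went from 0, 0 and 0.638 to 10.6, 16.3 and 12.4 FPKM (adjusted p = 0.00488), and Ear6, of the eosinophil-associated ribonuclease family, whose members are alike in sequence, from 0, 0.116 and 0 to 16.01, 44.9 and 34.6 FPKM (adjusted p = 0.00139). The largest fall was that of Igkc, the immunoglobulin kappa constant region (chromosome 6, 70726435 to 70726966, overlapping the predicted Gm30211), at 773.6, 746.1 and 865.8 FPKM in wild type and 0, 0 and 1.35 FPKM in KO (adjusted p = 2.08e-06).

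In all, 27 of 11837 tested genes passed an adjusted p of 0.05, 21 higher and 6 lower in the KO libraries. Besides the eosinophil genes, Dntt, the terminal transferase of lymphoid progenitors, rose from 1.37 ± 0.685 to 15.7 ± 3.67 FPKM (SD, n = 3), Gzmb, granzyme B, from 8.07 ± 1.33 to 48.2 ± 22.3, and Glrx5, a mitochondrial glutaredoxin of iron-sulfur cluster assembly, from 8.57 ± 1.79 to 28.9 ± 5.32. The leukocyte tetraspanin Cd53 rose 2.59-fold, from 32.1 ± 4.28 to 83.0 ± 7.11. Of the falling genes, Dnajb7, an intronless gene annotated inside Xpnpep3 on the opposite strand (chromosome 15, 81406926 to 81408299), went from 5.52, 5.45 and 6.35 FPKM to 0.113, 0 and 0. The G protein subunit gene Gng11 fell from 222.6 ± 10.2 to 94.6 ± 23.5 FPKM and Cavin1, a coat protein of caveolae, from 156.5 ± 13.4 to 77.9 ± 9.45. Snord35a, a small nucleolar RNA inside the ribosomal protein gene Rpl13a and on its strand, missed the threshold at 19.97 ± 5.12 and 4.87 ± 2.01 FPKM, with an adjusted p of 0.0754. It passed with a filter of mean FPKM of at least 5. At an unadjusted p of 0.05 there were 1089 genes, 576 higher and 513 lower, where 592 would be due to chance. Of these, 363 also changed at least 2-fold on the log2(FPKM + 1) scale, 158 higher and 205 lower. The groups did not overlap for 1802 genes, or 15.2%, where chance gives 10%.

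The test was limma on log2(FPKM + 1). Without wild-type library 1, 2 or 3 there were 13, 13 and 11 calls, of which 12, 10 and 9 were among the 27, and without KO library 1, 2 or 3 there were 19, 13 and 11, of which 16, 11 and 10 were. In each of these fits 7 of the 27 genes kept their call, namely Prg2, Prg3, Ear6, Epx, Igkc, Hbb-bt and Car1. Calls also fell to 8 without limma's variance trend, to 11 with the replicate number as a block and to 8 with limma-voom on recovered reads, chosen after seeing the data. With voom Prg2, Prg3, Ear6, Epx and Igkc kept their direction and had adjusted p of 0.189, 0.257, 0.418, 0.369 and 0.185.

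**Figure D1:**
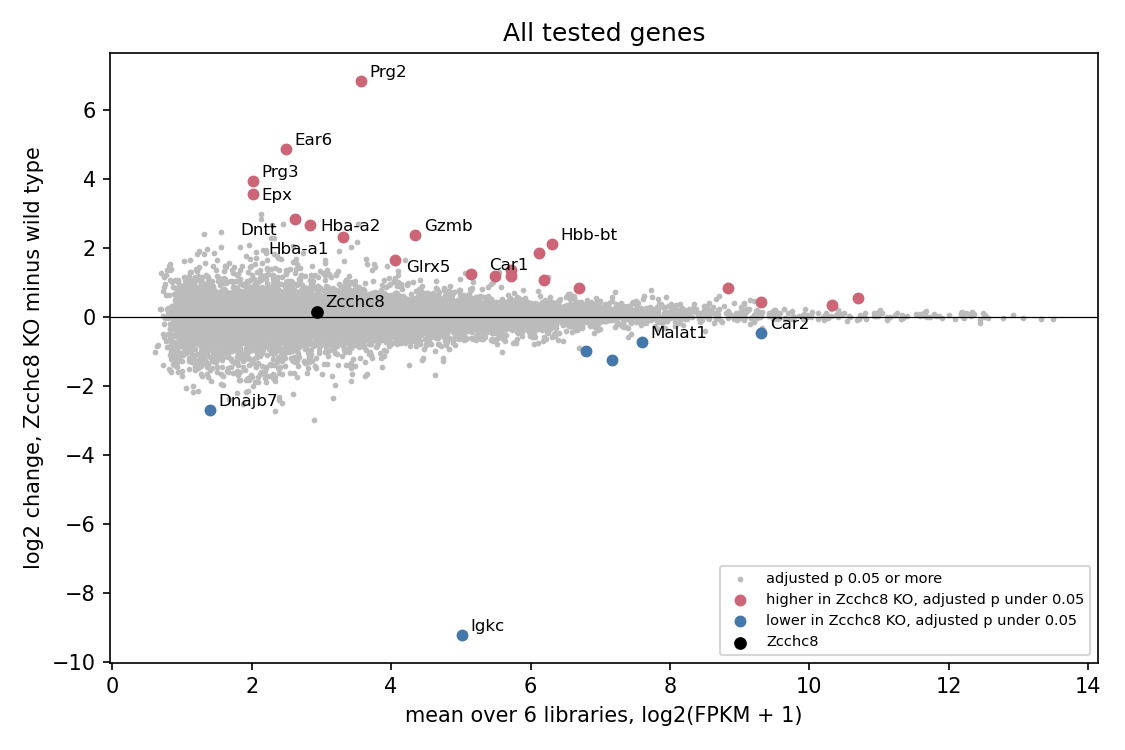
Log2 change of KO against wild type (vertical axis) by the mean log2(FPKM + 1) of the 6 libraries (horizontal axis) for the 11837 tested genes. Red points are the 21 genes called higher, blue points the 6 called lower and the black point Zcchc8, which lies near 0, while Prg2 lies highest and Igkc lowest.

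**Figure D2:**
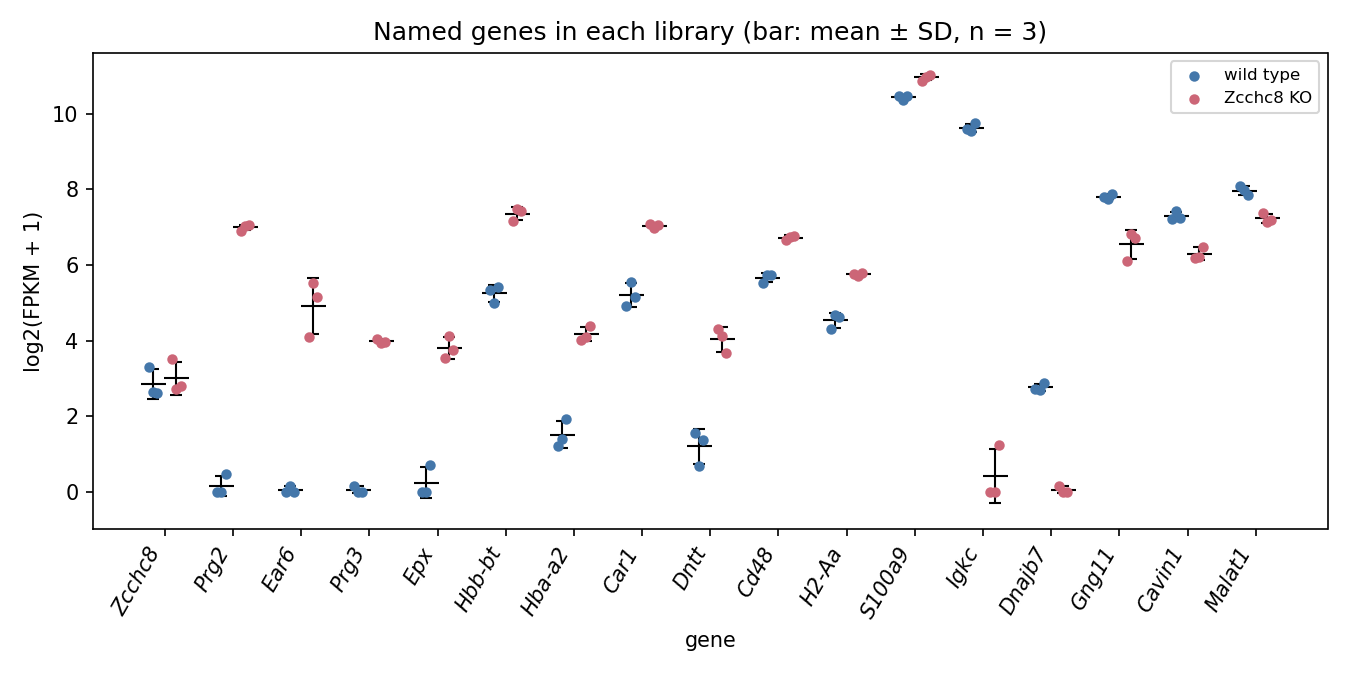
Level of 17 named genes as log2(FPKM + 1) in each library, with points for the 3 wild-type (blue) and 3 KO (red) libraries and black bars for the mean ± SD. The 4 eosinophil genes sit at or near 0 in every wild-type library and Igkc and Dnajb7 at or near 0 in the KO libraries, while the points of Zcchc8 overlap.

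The erythroid list passed camera as higher. Of 13 tested members 4 rose and 1 fell over all genes, and 8 rose and 1 fell adjusted over the list alone. The beta globin Hbb-bt (chromosome 7, 103812524 to 103813996) rose 4.38-fold, from 37.5 ± 5.73 to 164.4 ± 19.6 FPKM (SD, n = 3), the alpha globins Hba-a1 from 3.56 ± 1.17 to 21.4 ± 3.80 and Hba-a2 from 1.91 ± 0.762 to 17.1 ± 2.39, and Car1, the erythroid carbonic anhydrase, from 36.4 ± 8.61 to 131.0 ± 6.13. Car2, a carbonic anhydrase in the same list that stem cells express strongly, moved the other way, from 751.2 ± 35.6 to 536.5 ± 14.7 FPKM. The list had an adjusted p of 1.63e-08 by camera, and an adjusted p of 0.0632 with an estimated correlation. Hba-a1 and Hba-a2 are near-identical copies, as are the beta globins in large part, so the share of reads given to each copy is uncertain.

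Of the lists of other blood lineages, 4 more passed camera as higher, besides that of granulocytes, and 1 of these 4 also did with an estimated correlation. The list of monocytes, macrophages and dendritic cells had 2 of 6 tested members pass, the MHC class II genes H2-Aa (22.3 ± 2.99 to 53.1 ± 1.43 FPKM, SD, n = 3) and H2-Eb1 (29.0 ± 4.80 to 67.4 ± 9.94), and 5 rose adjusted over the list alone. The call of H2-Eb1 ended under 15 of 23 other settings and that of H2-Aa under 8. H2-Ab1 stood at 51.9 ± 3.65 and 88.5 ± 8.43 and the invariant chain Cd74 at 32.1 ± 5.09 and 48.3 ± 9.57 without passing over all genes. The list had an adjusted p of 3.94e-08 by camera and an adjusted p of 0.0451 with an estimated correlation. In the B cell list no member of 6 passed over all genes, 5 were higher at an unadjusted p of 0.05 and these 5 rose adjusted over the list alone, among them the surrogate light chain gene Vpreb1 (11.1 ± 5.99 and 26.8 ± 6.94 FPKM), Vpreb3 (7.45 ± 2.13 and 22.1 ± 6.33), the receptor component Cd79a (1.80 ± 2.12 and 7.83 ± 2.07) and Ighm (8.10 ± 3.18 and 14.9 ± 2.76). Its adjusted p was 0.000502 by camera, and an adjusted p of 0.0907 came with an estimated correlation. The list of lymphoid priming and multipotent progenitors had 2 of 9 members pass, Dntt and Cd48, a SLAM family surface protein low on long-term stem cells. Cd48 rose 2.10-fold, from 49.9 ± 4.05 to 104.8 ± 4.21 FPKM. Tcf3 stood at 17.1 ± 2.85 and 27.9 ± 2.31 FPKM. This list had an adjusted p of 0.00914 by camera and an adjusted p of 0.164 with an estimated correlation. The T and NK cell list passed camera at an adjusted p of 0.0382, with an adjusted p of 0.246 with an estimated correlation, and none of its 5 tested members passed over all genes, with 2 higher at an unadjusted p of 0.05. Nkg7 measured 201.5 ± 27.0 and 300.8 ± 10.3 FPKM and Cd3d 0.448 ± 0.775 and 3.80 ± 1.40, both passing adjusted over the list alone, Lck 7.28 ± 4.37 and 11.5 ± 2.29, and Klrb1c 1.998 ± 1.23 and 1.249 ± 1. The call of the T and NK cell list ended without wild-type library 1 or 2 or KO library 1 or 3 (adjusted p = 0.109, 0.0555, 0.0589 and 0.108), with median log2 changes of 0.60, 0.33, 0.57 and 0.59 against 0.58. It also ended without a filter, with a median of 0.20 (adjusted p = 0.0892), with the replicate block, with a median of 0.58 (adjusted p = 0.0514), after GC and length correction, with a median of 0.53 (adjusted p = 0.0504), and by fry (adjusted p = 0.0954). Gzmb was the 1 member of the 5 tested in the mast cell and basophil list to pass, and that list did not, with an adjusted p of 0.088, though it did without wild-type library 1 (adjusted p = 0.0374) or KO library 2 (adjusted p = 0.0413).

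Granulocyte genes moved both ways. Of 21 tested members 1 passed over all genes, S100a9, which rose from 1386 ± 56.8 to 2003 ± 108 FPKM (SD, n = 3), while 6 rose and 3 fell adjusted over the list alone. The rising 6 included the calprotectin gene S100a8 (482.5 ± 63.0 and 667.4 ± 40.7 FPKM), the neutrophil granule gene Ngp (337.7 ± 41.8 and 516.9 ± 67.7) and the ficolin gene Fcnb (12.7 ± 3.22 and 25.6 ± 2.80). The falling 3 were Mpo (67.5 ± 4.07 and 49.9 ± 4.65) and Prtn3 (254.6 ± 17.9 and 199.3 ± 16.1), enzymes of primary granules, and the myeloid transcription factor gene Spi1 (76.7 ± 9.89 and 52.8 ± 11.8), named here after their values were seen. The list passed camera as higher at an adjusted p of 0.0066, with an adjusted p of 0.13 with an estimated correlation. Its median log2 change of 0.47 went to 0.31 without wild-type library 2 and to 0.32, 0.23 and 0.22 without KO library 1, 2 or 3, where the preset call held.

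The list of stem cell identity genes passed camera as lower. None of the 35 tested members of the LT-HSC list passed over all genes and 2 fell adjusted over the list alone, among them Pdzk1ip1 (91.1 ± 6.10 and 57.9 ± 7.06 FPKM, SD, n = 3). At an unadjusted p of 0.05, 13 members were lower and 1 higher. The receptor gene Kit stood at 36.7 ± 3.97 and 23.3 ± 4.03 FPKM and Ndn, encoding necdin, at 19.8 ± 5.25 and 4.63 ± 4.54. The median log2 change of the list was -0.27, its adjusted p 0.000675 by camera, and an adjusted p of 0.08 came with an estimated correlation. The megakaryocyte list did not pass (adjusted p = 0.738), with 8 of its 16 tested members higher by value and 8 lower. In the endothelial and stromal list 3 members were above the expression filter and none passed.

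**Figure D3:**
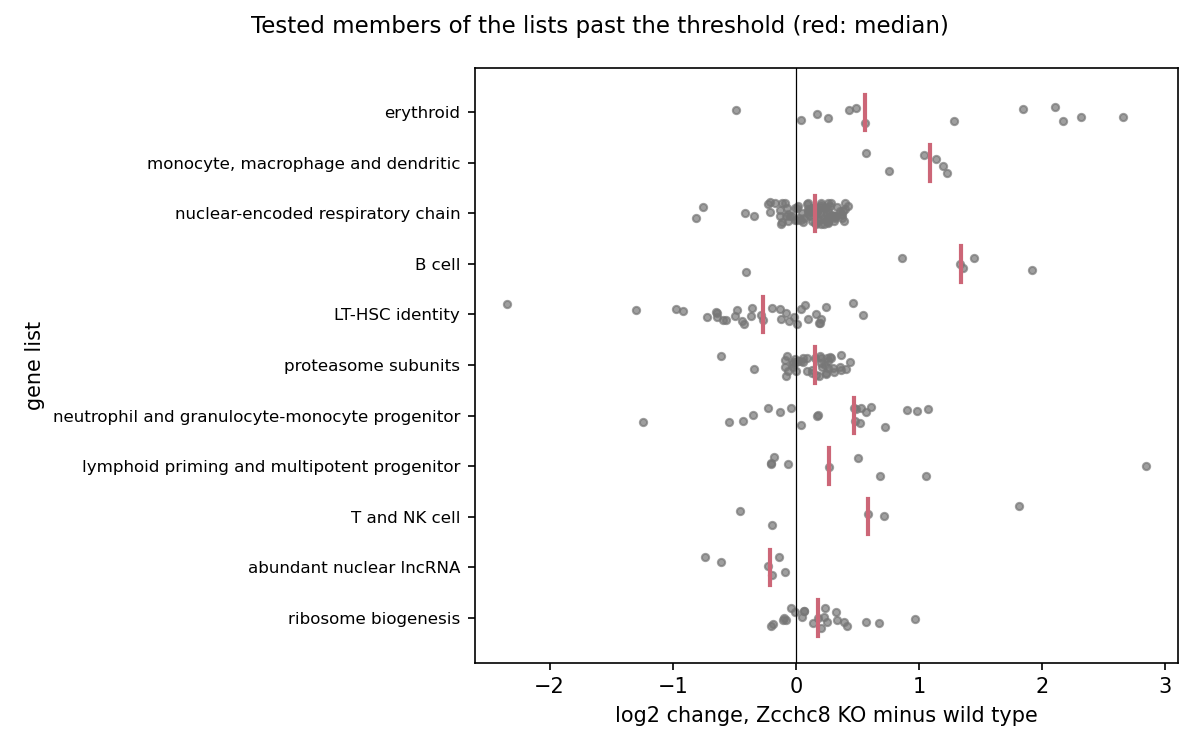
Log2 change of KO against wild type (horizontal axis) for each tested member (grey points) of the 11 gene lists past the camera threshold (vertical axis), with the list median in red. The medians of the LT-HSC and nuclear lncRNA lists lie below 0 and those of the other 9 lists above it, with members on both sides of 0 in most lists.

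The lists of the respiratory chain, the proteasome and ribosome biogenesis passed camera as higher, while glycolysis (adjusted p = 0.538) and cytosolic ribosomal proteins (adjusted p = 0.088) did not pass. The 88 tested genes of the nuclear-encoded respiratory chain had a median log2 change of 0.16, 66 of them higher by value, 14 of these at an unadjusted p of 0.05, and none passed over all genes or adjusted over the list alone. Uqcrfs1, the Rieske iron-sulfur subunit, stood at 153.0 ± 18.5 and 201.3 ± 5.46 FPKM (SD, n = 3), Ndufb6 at 107.8 ± 6.62 and 141.4 ± 14.1, the ATP synthase gene Atp5b at 264.6 ± 13.7 and 314.5 ± 0.745 and the pseudogene Ndufa12-ps, which the symbol pattern took in, at 287.0 ± 28.2 and 373.0 ± 47.5. The list had an adjusted p of 3.06e-05 by camera and an adjusted p of 0.0451 with an estimated correlation. The proteasome list had a median log2 change of 0.15 over 43 members, with no passing member and 4 higher at an unadjusted p of 0.05. Psmd8 measured 57.3 ± 8.71 and 76.2 ± 9 FPKM, Psma6 142.5 ± 10.7 and 168.9 ± 13.3, Psmd4 33.7 ± 2.41 and 43.5 ± 5.19 and Psma5-ps 206.3 ± 5.84 and 267.0 ± 20.7. Its adjusted p was 0.00295 by camera, and an adjusted p of 0.246 came with an estimated correlation. In ribosome biogenesis no member of 23 passed and 2 were higher at an unadjusted p of 0.05, with the nucleolar genes Npm1 at 116.3 ± 5.85 and 137.2 ± 4.25 FPKM, Utp4 at 8.90 ± 3.08 and 14.4 ± 1.85, Nat10 at 2.76 ± 2.36 and 5.62 ± 1.54 and Mybbp1a at 12.6 ± 1.10 and 16.8 ± 1.57. The list had an adjusted p of 0.0382 by camera and an adjusted p of 0.352 with an estimated correlation. Its call ended without wild-type library 1 or 3 or KO library 1 or 2 (adjusted p = 0.236, 0.0506, 0.0985 and 0.136), and also with a mean FPKM of at least 5 (adjusted p = 0.123), under quantile scaling (adjusted p = 0.0508) and by fry (adjusted p = 0.156). The call of the proteasome list ended without wild-type library 3 (adjusted p = 0.0671) and by fry (adjusted p = 0.156). Its median went from 0.15 to 0.10 without wild-type library 2 or 3.

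The list of abundant nuclear long noncoding RNAs passed camera as lower. Malat1, the most abundant of them (chromosome 19, 5795690 to 5802672), fell 1.67-fold, from 250.6 ± 20.6 to 149.7 ± 12.7 FPKM (SD, n = 3), the 1 passing member of 6. Meg3 stood at 2.63 ± 0.192 and 1.45 ± 0.743 FPKM, Kcnq1ot1 at 1.48 ± 0.445 and 1.11 ± 0.240 and Neat1 at 4.85 ± 0.615 and 4.30 ± 0.289. The list had an adjusted p of 0.0382 by camera and an adjusted p of 0.253 with an estimated correlation. Its call ended without wild-type library 2 or 3 or KO library 1 or 2 (adjusted p = 0.208, 0.0505, 0.132 and 0.0993), with median log2 changes of -0.14, -0.26, -0.16 and -0.28 against -0.21. The call held without wild-type library 1 or KO library 3, with medians of -0.33 and -0.34. It also ended after GC and length correction, with a median of -0.11 (adjusted p = 0.108), under quantile scaling, with a median of -0.15 (adjusted p = 0.0508), with the replicate block, with a median of -0.21 (adjusted p = 0.0522), and by fry (adjusted p = 0.127).

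By annotated class, the 1177 tested pseudogenes passed as higher, with a median log2 change of 0.07, an adjusted p of 0.0453 by camera and an adjusted p of 0.00319 with an estimated correlation. The processed pseudogenes Gm20203 (342.8 ± 17.2 to 611.3 ± 69.7 FPKM), Gm5121 (76.1 ± 4.93 to 137.8 ± 16.4) and Gm11964 (545.6 ± 15.3 to 740.3 ± 30.4) rose. Their calls ended under 5, 14 and 13 of 22 other settings. An aligner that does not split reads over introns can place parent mRNA on such copies. The class lost its call under 13 of 23 other settings, with adjusted p from 0.00319 to 0.882 over all of them. The median changed most after GC and exon length correction, from 0.066 to 0.017 (adjusted p = 0.882), and stood at 0.034 under TPM (adjusted p = 0.21) and 0.038 without a filter (adjusted p = 0.13). The call also ended under median-of-ratios and quantile scaling and with the removal of any library but KO library 2 (adjusted p = 0.0679, 0.0666, 0.0872, 0.109 and 0.0629). Of 1529 tested predicted transcripts without a name 4 rose, and that list did not pass camera (adjusted p = 0.215, and an adjusted p of 0.0451 with an estimated correlation). By fry that list passed (adjusted p = 0.0117). The 287 long noncoding RNAs (adjusted p = 0.194) and the 102 small RNAs (adjusted p = 0.0803) did not pass camera, and neither did single-exon coding genes (adjusted p = 0.373) or the class of genes with the shortest span, up to 6091 bp (adjusted p = 0.0868, and an adjusted p of 0.00319 with an estimated correlation). By camera the small RNAs did pass as lower without wild-type library 2 (adjusted p = 0.0278) or KO library 2 (adjusted p = 0.0285). By fry the long noncoding RNAs passed (adjusted p = 0.00669, median log2 change -0.115), as did the small RNAs (adjusted p = 0.0449, median -0.25). The pseudogenes (adjusted p = 0.00065) and the shortest span (adjusted p = 0.000789) also passed by fry, and single-exon coding genes did not (adjusted p = 0.318). The values are per gene symbol and from polyadenylated RNA, so the table may hold few of the short-lived nuclear transcripts that the complex acts on. Those without a symbol of their own are not measured here.

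The lists of R-loop processing, p53 target and DNA repair genes did not pass. They give RNA levels of these genes and do not measure R loops or DNA damage. The 29 tested R-loop processing genes had a median log2 change of -0.01 and no member with an unadjusted p under 0.05 (camera adjusted p = 0.784). Of 21 p53 targets 1 was higher and 2 lower at that level, and none passed over all genes (adjusted p = 0.784). Homologous recombination and Fanconi anaemia genes (adjusted p = 0.617) and end joining and base excision repair (adjusted p = 0.707) did not pass either. The same held for type I interferon response (adjusted p = 0.366), nucleic acid sensing (adjusted p = 0.617), DNA replication (adjusted p = 0.342) and mitosis genes (adjusted p = 0.307), and for a list of genes raised in aged stem cells (adjusted p = 0.707). Mean, median and test differed in sign in 6 lists that did not pass, those of telomerase, NF-kB, megakaryocytes, histones, p53 targets and quiescence. In simulated tables of this design 19.5% of genes changed by 1 on the log2 scale and 61.6% of those changed by 2 were recovered, so a single gene that did not pass may still differ by 2-fold.

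More genes of the table were at 0 in KO than in wild type. There were 549, 508 and 513 such genes in the wild-type libraries 1 to 3 and 819, 832 and 810 in the KO libraries, although each KO library had more reads behind its values than any wild-type library. The table holds no gene at 0 in all 3 libraries of a group, so a gene switched off throughout 1 group is not measured here. Libraries of 1 group correlated at r = 0.9323 to 0.9386 across genes, and those of different groups at 0.9252 to 0.9279. The first principal component, with 26.2% of the variance, separated the groups. The next components, with 19.9% and 19.3%, set the KO libraries apart from each other, at 41.89, -14.38 and -31.7 on component 2 and -9.67, 41.64 and -33.72 on component 3. The wild-type libraries lay between -3.84 and 10.34 on component 2 and between -4.39 and 3.65 on component 3.

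**Figure D4:**
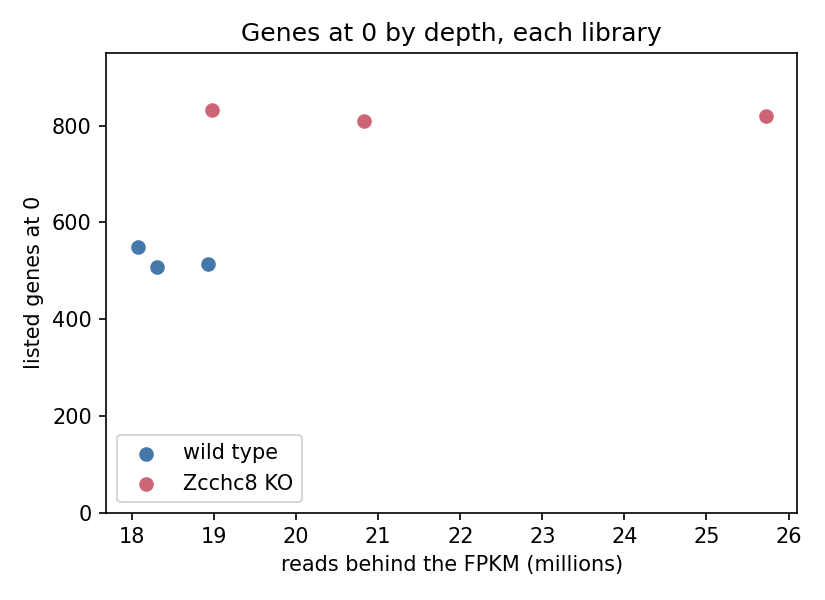
Number of listed genes at 0 FPKM (vertical axis) by the reads behind the FPKM (horizontal axis, in units of 1e+06 reads), 1 point per library. The 3 wild-type libraries (blue) have 508 to 549 genes at 0 and the 3 KO libraries (red) 810 to 832.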

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

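Voom, the GC and length correction, the removal of pseudogenes and equal depth were chosen after seeing the data. Every one of the 27 called genes kept its direction in each setting where it was tested. Of the 27 calls, 23 held under each of TPM, median-of-ratios and quantile scaling and 25 under each pseudocount. Only 1, that of Hbb-bt, held under every setting. Among the named genes, Glrx5, Car2, Malat1, H2-Aa, H2-Eb1, Gm5121 and Gm11964 lost the call whichever library was left out. The main counts were 27 genes, 21 higher and 6 lower. Without the variance trend limma called 8, 6 higher and 2 lower, and voom on recovered reads 8, 5 higher and 3 lower, 7 of them among the 27. Without a filter 3 genes were lower. Leaving out 1 library each gave 11 to 19 genes, 8 to 14 higher and 1 to 5 lower, with fewer samples. The 363 genes at 2-fold and unadjusted p became 73 with a pseudocount of 5, which shrinks low genes, and 162 with a mean FPKM of at least 5, from fewer genes, and ranged from 401 to 472 without 1 library. The log2 change of Zcchc8 ranged from -0.11 to 0.37 without 1 library. The 11 lists became 3 with an estimated correlation and 8 to 11 without 1 library. The 1 class became 0 with a pseudocount of 5, without a filter, under TPM, median-of-ratios and quantile scaling, without ribosomal protein and mitochondrial genes, where the rest was also rescaled to a fixed total as in TPM, under voom, after GC and length correction and, by construction, without pseudogenes, 3 with an estimated correlation, and 0 to 2 without 1 library; the cause was not tested where none is named.

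With the replicate number as a block limma called 11 genes, 10 higher and 1 lower, and 9 lists. The deviations of same-numbered libraries correlated at 0.024, 0.007 and 0.004, and 3 of the 6 libraries correlated best with their own number. These values show no clear pairing by number and cannot exclude that same-numbered samples were handled together.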

Other observations

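The tests of granule stage, of the 8 cell type lists, of lists without each KO library, of B cell genes and of the SD ratio without libraries were chosen only after the result was seen, and the intervals around the percentile, the share of kept calls and the SD ratio were added after these had been seen to lie at or near their bounds. The small RNA, H/ACA, histone and platelet genes named here were also chosen after their values were seen, and none passed over all genes by limma. Small structured RNAs went both ways, with 4 of 31 tested members lower and 2 higher adjusted over the list alone. Polyadenylated RNA was sequenced. Whether reads at small RNA and histone genes, here and above, come from the mature RNAs or from longer or tailed forms was not tested. Snord23 stood at 6.51 ± 2.13 FPKM in wild type and 0.587 ± 1.02 in KO (SD, n = 3), Snora78 at 18.5 ± 4.29 and 5.44 ± 2.70 and Snora31 at 114.3 ± 32.9 and 68.9 ± 7.45, while the Y RNA gene Rny3 stood at 0.346 ± 0.599 and 6.03 ± 1.76. In the telomerase list, 2 genes of the H/ACA particle that guides pseudouridylation rose adjusted over the list alone, Gar1 (30.6 ± 7.52 and 59.4 ± 5.49) and Nhp2 (151.6 ± 13.2 and 205.4 ± 15.7). Among replication-dependent histone genes 3 of 49 rose adjusted over the list alone, H4c9 (176.1 ± 4.08 and 260.9 ± 21), H2ac13 (8.57 ± 3.01 and 25.3 ± 7.60) and H3c1 (2.82 ± 2.10 and 10.1 ± 0.751). The platelet factor gene Pf4 stood at 162.2 ± 33.1 and 276.2 ± 17.1 FPKM. The camera adjusted p of the small RNA list was 0.064, of the telomerase list 0.617 and of the histone list 0.336. The small RNA list passed as lower without wild-type library 2 (adjusted p = 0.00761), without KO library 1 (adjusted p = 0.0136) and at equal depth (adjusted p = 0.0486), with adjusted p from 0.00761 to 0.494 over its alternatives. The telomerase list passed with a mean FPKM of at least 5 (adjusted p = 0.0421), with a range from 0.0421 to 0.993.

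With the preset correlation 6 lists of blood lineages passed as higher and the LT-HSC list as lower, and with an estimated correlation only the list of monocytes, macrophages and dendritic cells kept its call (adjusted p = 0.0451), the others having adjusted p from 0.0632 to 0.246. By fry the calls held for erythroid (adjusted p = 0.00955), monocyte, macrophage and dendritic (0.00198) and B cell genes (0.0123). They also held for granulocyte (adjusted p = 0.02), lymphoid priming (0.0117) and LT-HSC genes (0.00789). That of T and NK cells ended by fry (adjusted p = 0.0954). After removal of each library's trend with GC content and exon length, 17 of the 21 genes called higher kept the call, or 81% (exact 95% interval 58.1 to 94.6), barely past the bound of 80% set in advance against that trend as the whole source. An even gain of all other marrow cell types is not decided by the difference between 8 fixed lists of such types (permutation p = 0.00693, 73 genes). A gain moves markers of high level less on the log2 scale. The mean log2 change of 6 late granule genes exceeded that of 4 primary ones by 0.657 ± 0.161. Such a smaller step does not account for the falls of the primary genes Mpo (log2 change -0.431) and Prtn3 (-0.352), while Elane (-0.036) and Ctsg (0.182) moved less. As these genes were grouped after their values were seen, they leave the even gain undecided. Stray cells in 1 KO library as the source of the calls of the lineage lists are argued against by 5 of the 6 lists, which stayed past the threshold without each KO library in turn, while T and NK cells did not. Not decided are stray mature cells for the 39 raised single genes, whose within-KO coefficient of variation had a median percentile of 50 (95% interval 35.5 to 60.5), 8 being above the 75th, among them Gzmb at 99 and Ear6 at 98.5, since they had passed a test that favours a low spread, and, untested, a gain of particular cell kinds in all 3 KO sorts, of which lineage depletion would remove those with lineage markers, and a change of expression within the stem cells tied to the genotype.

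Igkc reads were lost in KO, with 23412 recovered reads in the wild-type libraries and 15 in the KO libraries. B-lineage cells in the wild-type libraries alone would lower other B cell genes in KO, but 6 of them had a mean log2 change of 1.08 ± 0.33 (SE over genes). These 6 are the tested members of the B cell list, already seen to be higher, so the value is no separate test. They include the surrogate light chain gene Vpreb1, and a small share of kappa-expressing cells in wild type is not decided by them. For plasma cells the 9 tested genes, of 13 listed, had a mean log2 change of 0.014 ± 0.081, with Mzb1 at 1.24 and 1.80 FPKM and Xbp1 at 109.5 and 126.6 in wild type and KO, and as all 9 were expressed in both groups a small share of such cells, which would have to escape the sort for stem cells, cannot be told apart. A difference of the chromosome 6 region between the animals of the groups may underlie it, and 16.7% of 30 genes within 2 Mb had an unadjusted p under 0.05, against 9.2% of all tested genes, which lies between the bounds set in advance and leaves it open. The table holds no gene at 0 in all 3 libraries of a group, so B or plasma cell markers absent throughout KO would not be seen. A link of the Igkc loss to the genotype was not tested.

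More genes were at 0 in the KO libraries. All libraries were thinned to the same number of reads over the 14693 genes matched to the annotation, fewer than in the counts above. The KO library with the fewest genes at 0 then had 821 and the wild-type library with the most had 537, a gap of 284, which argues against depth as the source. Fewer distinct molecules in the KO libraries may be the source, and the within-group SD of genes with mean FPKM of 1 to 10 was 1.051 times as large in KO as in wild type at the median (95% interval 1.03 to 1.073 by a bootstrap over genes, which does not cover the spread between libraries). Leaving out 1 library of each group gave 1.029 to 1.087, a range that spans the bound set in advance, which the value itself barely passes. The ratio does not decide the question, as a gene at 0 in only some KO libraries has a wider KO SD whatever the cause. A difference of the genotype in lowly expressed genes stays open and was not tested.

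The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 27 genes and the highest of the others 1, and for 2-fold changes the values were 363 and 230. It gave 11 lists and the others at most 1, and 1 class and the others 0. In each case 1 split, the real one, gave a count as large.

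Within 10 Mb of Zcchc8, 12 of 160 tested genes (7.5%) had an unadjusted p under 0.05, against 9.2% of other genes (Fisher's exact test, p = 0.581), and none passed. Over 180 pairs of a pseudogene and its parent by symbol, the log2 changes correlated at r = 0.17 across genes, which are not independent replicates. Siglecf, an eosinophil surface lectin chosen after its values were seen, stood at 1.79 FPKM in wild type and 6.12 in KO and did not pass over all genes (limma adjusted p = 0.492).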
